A study of Mus musculus with 7 samples.

How the data were processed

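RNA was measured in 7 kidneys of male Slc7a9-/- mice, 3 untreated and 4 treated with L-ergothioneine at 16 mg/kg/day, all aged 6 months. Per the labels' protocols, total RNA came from frozen kidney, ribosomal RNA was depleted, and stranded libraries were made by adapter ligation with 10 cycles of amplification. Per the submitters' processing notes, the tools were FastQC 0.11.9, Trim Galore 0.6.7, cutadapt 3.4, STAR 2.7.10a, RSEM 1.3.1, Salmon 1.10.1, Picard 3.0.0, SAMtools 1.17, StringTie 2.2.1, bedtools 2.30.0, Subread 2.0.1 with featureCounts, MultiQC and DESeq2, and the builds GRCm38 and mm10. The notes give no role, order or setting for them, and the annotation release and the strand setting of the counting are not given in the sources used here.

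The authors deposited a table of expected counts and a table of TPM for 45706 Ensembl genes, with a column per mouse. The deposited expected counts are estimates, and 3.61% of the values were not whole, so reads shared between similar genes were split by the authors' counting. Levels of near-identical copies, such as the glutathione transferases, the Slc22a28 and Slc22a30 pair, immunoglobulin genes and small nuclear RNA copies, are therefore uncertain. The deposited TPM values are scaled to a fixed sum per library after division by transcript length, so short RNAs weigh more there than in the counts. Column names matched the library names in the labels for all 7 samples. Symbols and positions came from GENCODE release M21 (GRCm38), which held 45143 of the 45706 gene identifiers, and list symbols absent there were looked up among the synonyms of the RefSeq table of GRCm38.

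Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM scaling, and the robust quasi-likelihood F test of treated against untreated, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of F. After the filter 15399 genes remained. CPM values use the TMM library sizes and are given as mean ± SD. Library totals of 14843899 to 19791575 counts gave a median standard error of 0.11 log2 units per tested gene. Pairs of libraries within a group differed by 7.98 to 27.6 times the sampling noise of their counts (chi-square per degree of freedom), so no library was a copy of another.

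Before the data were examined, 42 gene lists (23 pathways and 19 cell types), the tests, the alternatives and the rule for named genes were fixed. Lists with at least 3 tested members, 39 in all, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation, on ranks and on log2(TPM + 1), and fry. Each list's members were also adjusted over the list alone. The rule names 12 genes of the study's subject in every case and the 12 largest changes per direction among genes past the threshold, with groups that do not overlap and a mean log2 CPM of at least 0. It adds up to 4 members past the threshold per list, and 4 members in the list's direction per called list. Predicted genes and genes without a symbol were counted and not named, and 5 list members were kept in every list count and test but are not reported by name here. Other members behind a small count, further clock and adipocyte genes, Gclm and the genes of the closing section were named after their values were seen.

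The alternatives were DESeq2 1.42.0, limma-voom with and without sample weights, other scalings and filters, each library left out in turn, the replicate number and the range of library index numbers as blocks, limma-trend on TPM with pseudocounts of 1 and 0.1, other thresholds, and counts without mitochondrial and haemoglobin genes. Leaving out untreated libraries 1 and 2, and leaving out short non-coding genes (median transcript under 400 nt, not protein-coding), were added after seeing the data, as were the list counts without each library. All 35 splits of the 7 libraries into 3 and 4 were fitted in the same way.

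The tests were tested on simulated data: 5 sets of counts for the 15399 genes of this comparison, with the same 200 changed genes in each. Genes varied independently in these sets and no library effect was simulated, unlike in real kidneys. By edgeR 20.4% of the changes of 1.25-fold, 62.8% of 1.5-fold, 75.6% of 2-fold and 89.6% of 4-fold were recovered, all in the right direction, and 7.45% of the calls were unchanged genes. With no gene changed, 0 of 39 lists were called, in data where genes varied independently.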

Results

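The series measured kidney RNA of 7 male Slc7a9-/- mice aged 6 months. Slc7a9 encodes the light chain of the renal cystine transporter, and mice without it are a model of cystinuria, in which cystine is lost into the urine and forms stones. Of the 7 kidneys, 3 were untreated and 4 came from mice that drank water with L-ergothioneine, a sulfur-containing antioxidant taken up from the diet, at 16 mg/kg/day. The single comparison of the design asks how the kidney transcriptome of this model differs with ergothioneine. Libraries held between 14843899 and 19791575 counts, and 15399 of the 45706 genes in the tables had enough counts to be tested. The labels number the mice within each group but give no litter, cage or time of collection. The p-values set the group difference against the spread among kidneys of the same group. They cannot show whether litter, cage or time of collection coincided with the groups. All samples carried the same genotype, so no value compares the model with wild-type kidney.

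Slc7a9 itself (chromosome 7, 35448796 to 35466036, GRCm38) had 98, 95 and 105 counts in the 3 untreated libraries and 119, 166, 162 and 103 in the 4 treated ones. This equalled 6.22 ± 0.603 CPM (counts scaled to equal library size; SD, n = 3) untreated and 7.56 ± 1.71 (SD, n = 4) treated. Slc3a1, which encodes its heavy-chain partner, stood far higher at 751 ± 29.1 and 722 ± 37.5 CPM. Neither gene passed the test between the groups (edgeR, log2 fold change 0.28 ± 0.17 (SE), adjusted p = 0.378 for Slc7a9 and -0.06 ± 0.06, adjusted p = 0.692 for Slc3a1). The labels do not say which part of Slc7a9 was disrupted, so these counts cannot check the genotype. In the deposited TPM values the direction for Slc7a9 was opposite, with 18.7, 12.69 and 9.37 TPM untreated against 9.59 to 11.82 TPM treated.

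Ergothioneine-treated kidneys differed from untreated ones in 1102 genes, of which 552 were higher and 550 lower. Most differences were small: the median absolute log2 fold change of these genes was 0.39, and 128 of them changed at least 2-fold (55 higher, 73 lower). Among genes with a mean log2 CPM of at least 0 whose groups did not overlap, the steepest rises were those of Aqp8, a water channel (log2 fold change 3.09 ± 0.46), the clock activators Npas2 and Arntl (2.88 ± 0.18 and 2.80 ± 0.18) and the mitotic kinase Cdk1 (2.40 ± 0.52). Ccnb1 (2.06), Pbk (1.89), the prothrombin gene F2 (1.88), Hist1h3b (1.69), Mas1 (1.67), Iqgap3 (1.65), Insc (1.57) and Esco2 (1.53) followed. The steepest falls were in Ucp1, the uncoupling protein of brown fat (-4.65 ± 0.58), and in the fat droplet and adipocyte genes Cidea (-4.63 ± 0.50), Plin1 (-3.23 ± 0.32), Adipoq (-2.87 ± 0.40) and Cidec (-2.25 ± 0.32). Ighg2b (-2.75), Nat8l (-2.66), C4a (-2.35), Ciart (-2.31), Per2 (-2.29), Ugt2b37 (-2.07) and Col19a1 (-1.98) completed this group. Levels were low for some of these 24 genes, such as Aqp8 at 0.41 to 1.39 log2 CPM in the treated libraries. Adjusted p-values of the 24 ran from 5.33e-08 for Per2 to 0.0306 for Mas1 by edgeR. Without single libraries 4 of them missed the threshold: Cdk1 (adjusted p = 0.0531 without untreated library 2 and 0.0528 without untreated library 3), Iqgap3 (0.0599 and 0.0717 without the same libraries), Mas1 (0.0571, 0.105, 0.0659 and 0.0798 without untreated libraries 2 and 3 and treated libraries 1 and 3) and Pbk (0.0966 and 0.0712 without untreated libraries 1 and 3, and too few counts to be tested without treated library 2, 3 or 4).

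The groups did not overlap in 18.6% of the genes tested, where chance gives 5.71%, and the first principal component, with 37.0% of the variance, separated them. The count was 692 without treated library 1, 710 without treated library 2, and 556 (249 higher, 307 lower) against untreated library 3 alone. On log2(TPM + 1) values 1347 genes were called with 42 higher and 1305 lower, while the median gene lay 0.33 log2 units lower in the treated kidneys. This shift followed short non-coding RNA, which took 12.2% and 16.2% of TPM in untreated libraries 1 and 2 and 37.5% to 48.7% in the other 5 libraries. Of the counts it took 0.428% and 0.571% in untreated libraries 1 and 2 and 1.83% to 2.79% in the other 5. Directions below therefore come from the counts, and every log2(TPM + 1) value given beside them is subject to this shift.

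Of the 39 lists tested, the circadian clock genes had the smallest camera p. Of 20 tested members 3 rose, 14 fell and 3 did not pass, with the same 3 and 14 when adjusted over the list alone. Arntl, which encodes the core activator BMAL1, rose from 1.63 ± 0.515 to 11.6 ± 0.685 CPM, and Npas2, which encodes its partner, from 1.64 ± 0.449 to 12.2 ± 1.64 CPM. Clock rose less (log2 fold change 0.28, adjusted p = 0.0086). In the opposite direction, the repressor gene Per2 fell from 83.8 ± 3.33 to 17.1 ± 3.10 CPM (SD, n = 3 and 4) and Per3 from 86.4 ± 8.78 to 34.6 ± 2.00 CPM. Falls also passed for Ciart (-2.31 ± 0.19), Dbp (-1.84), Bhlhe41 (-1.54), Bhlhe40 (-0.96), Tef (-0.80 ± 0.07), Cry1 (-0.79), Nr1d2 (-0.65), Usp2 (-0.65), Hlf (-0.51), Cry2 (-0.47) and Rora (-0.24). Per1 (-1.03 ± 0.45, edgeR adjusted p = 0.292), Nr1d1 (-0.29, 0.445) and Nfil3 (-0.35, 0.788) did not pass. The list was lower by camera (adjusted p = 1.73e-27) and remained so with an estimated correlation (adjusted p = 0.00803). Cry1 lost its call without untreated library 1 (adjusted p = 0.0711) and Bhlhe40 without untreated library 2 (0.0593) or treated library 2 (0.0547). No time of day is given for the collections.

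**Figure D1:**
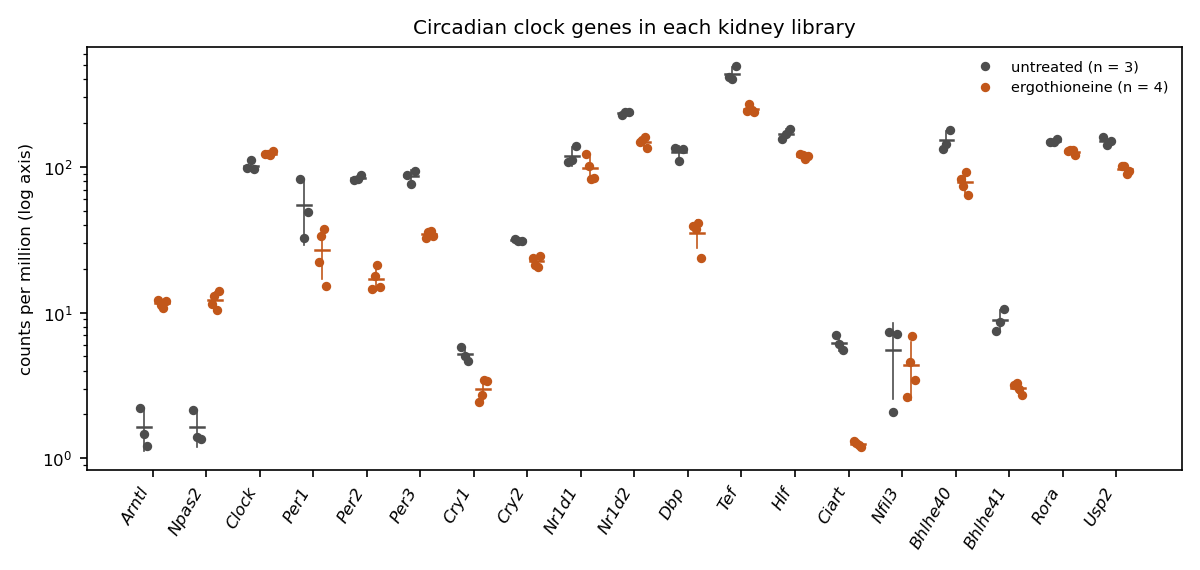
CPM (log axis) of 19 clock genes in the 3 untreated and 4 treated kidney libraries; points are libraries, horizontal lines means and vertical lines SD. Arntl and Npas2 lay at 1.22 to 2.21 CPM in untreated and 10.3 to 14.1 CPM in treated libraries, while Per2, Per3 and Ciart lay lower in every treated library.

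Genes of the antioxidant response regulated by NRF2 were higher in treated kidneys. In this list 11 of 29 tested members rose and 2 fell (14 and 2 when adjusted over the list alone). Nqo1, a quinone reductase, rose from 45.9 ± 6.56 to 90.1 ± 5.08 CPM (SD, n = 3 and 4; log2 fold change 0.97 ± 0.08, edgeR adjusted p = 3.78e-06). The glutathione transferase Gsta3 (0.68 ± 0.07), thioredoxin reductase Txnrd1 (0.50 ± 0.05), the pentose phosphate enzyme Pgd (0.49 ± 0.07) and the heme oxygenase Hmox1 (0.41 ± 0.09, adjusted p = 0.0099) rose as well. The 11 risen became 9 without untreated library 1, treated library 1 or treated library 2, and 12 without treated library 4. On log2(TPM + 1) Nqo1 kept its call, while Gsta3, Txnrd1, Pgd and Hmox1 lost theirs. The 2 that fell were Osgin1 (-0.58) and Me1 (-0.23). Me1 lost its call without any library except untreated library 3 (adjusted p up to 0.218), and Osgin1 without untreated library 3 or treated library 2 or 4 (up to 0.0751). Some risen members not named here were unstable too, with calls lost in up to 4 of these settings (edgeR adjusted p up to 0.117). The glutathione synthesis genes Gclc and Gclm stood at -0.16 ± 0.16 and -0.03 ± 0.06 (adjusted p = 0.661 and 0.83). Without untreated library 3 Gclc passed as lower (0.0054). Slc7a11, which encodes the cystine-glutamate exchanger, had at most 13 counts in a library and was not tested. The list's camera adjusted p was 9.14e-11, and the adjusted p was 0.135 with an estimated correlation.

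Antioxidant enzymes partly overlap that list, and 4 of 31 rose, also when adjusted over the list alone. They were Txnrd1, the sulfiredoxin Srxn1 (0.51 ± 0.07), and the glutathione peroxidases Gpx6 (0.51 ± 0.09) and Gpx4 (0.35 ± 0.07, which was -0.04 on log2(TPM + 1)). Camera gave adjusted p = 0.0019, 0.325 on log2(TPM + 1), and with an estimated correlation adjusted p = 0.175. In glutathione and sulfur amino acid metabolism 5 of 30 genes rose and 0 fell (7 and 1 when adjusted over the list alone, and 1 fell without untreated library 3 or treated library 3). Ethe1, the mitochondrial persulfide dioxygenase, gained 0.67 ± 0.07 (edgeR adjusted p = 1.40e-05) and the glutathione reductase Gsr 0.39 ± 0.06, beside Got1, Mtr and Dpep1. Got1 lost its call without any library except untreated 3 and treated 3 (adjusted p up to 0.1), Mtr without any except treated 3 (up to 0.1) and Dpep1 without any except untreated 1 and treated 4 (up to 0.177), and Got1 and Mtr were -0.14 and -0.08 on log2(TPM + 1). This list did not pass camera (adjusted p = 0.381), and its median of -0.07 had the opposite sign to its mean of 0.02.

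Transporters moved in both directions. Slc22a4, whose product OCTN1 carries ergothioneine, fell from 46.4 ± 4.65 to 35.9 ± 1.74 CPM (log2 fold change -0.37 ± 0.08, edgeR adjusted p = 0.00577, lower in all 4 treated libraries than in any untreated one). Slc7a13, which encodes the cystine and glutamate transporter AGT1 of the straight proximal tubule, fell from 921 ± 124 to 625 ± 51.0 CPM (-0.56 ± 0.09, adjusted p = 0.000967). Among renal amino acid transporters 5 of 28 rose and 4 fell (8 and 5 when adjusted over the list alone). The rises were in Slc43a2 (0.58), Slc7a8 (0.39 ± 0.07), Slc16a10 (0.33), Slc6a13 (0.32) and Slc3a2 (0.26), and the falls in Slc36a2 (-2.94 ± 0.41), Slc7a13, Slc6a20a (-0.55 ± 0.09) and Slc6a20b (-0.36). Slc36a2, also known from brown fat, moved with the adipocyte genes described below. The list did not pass camera (adjusted p = 0.119), with a median of 0.16 and a mean of -0.02. Of 23 organic ion transporters 1 rose, Abcc2 (0.33), and 3 fell, Slc22a30 (-0.61 ± 0.07), Slc22a28 (-0.42 ± 0.08) and Slc22a4 (1 and 5 when adjusted over the list alone; camera adjusted p = 0.107). Without treated library 3 or 4 the fallen were 5 and 6, and without treated library 4 the risen were 2. Abcc2 lost its call without untreated library 2, untreated library 3 or treated library 2 (0.055, 0.058 and 0.0546) and was -0.33 on log2(TPM + 1).

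Lipid genes split by pathway. Cholesterol biosynthesis was higher, with 8 of 25 members risen and 0 fallen (13 and 0 when adjusted over the list alone). Fdft1, the squalene synthase, rose from 16.5 ± 1.09 to 28.2 ± 4.26 CPM (log2 fold change 0.78 ± 0.11, edgeR adjusted p = 0.000382), and Dhcr7 and the regulator Srebf2 by 0.61 ± 0.10 and 0.45 ± 0.06. Without untreated library 3, 5 members rose. The list's adjusted p was 2.58e-12 by camera, and adjusted p = 0.189 with an estimated correlation. Fatty acid oxidation and PPARA targets were lower, with 6 of 36 fallen and 0 risen (10 and 0 when adjusted over the list alone). Acot12, an acetyl-CoA hydrolase, fell from 242 ± 31.4 to 167 ± 13.4 CPM (-0.53 ± 0.08, adjusted p = 0.00154), Eci1 by -0.34 ± 0.07 and the receptor gene Ppara by -0.58 ± 0.11. Camera gave adjusted p = 0.000116 for this list, 0.0746 without untreated library 1, and adjusted p = 0.522 with an estimated correlation, and fry did not call it (0.203). Ppara itself lost its call without untreated library 1 (adjusted p = 0.0504), where 2 members of the list fell, and 3 fell without treated library 1 or 2 (1 rose without untreated library 2).

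In gluconeogenesis and glycolysis 4 of 25 genes rose and 5 fell (10 and 6 when adjusted over the list alone). Pck1, the rate-limiting enzyme of gluconeogenesis, fell from 1888.91 ± 370 to 809 ± 42.9 CPM (log2 fold change -1.22 ± 0.11, edgeR adjusted p = 6.79e-05), together with Hk2 (-1.80), Pcx (-0.50), Pklr (-0.32) and Fbp1 (-0.29). Pfkp (0.51 ± 0.07), Pkm (0.46 ± 0.06) and the glucose transporter Slc2a1 (0.40 ± 0.07) rose, as did Tpi1 (0.20). Fbp1 missed the threshold without untreated library 1 (0.0734), Pklr without untreated library 1 or treated library 1 (up to 0.0706), and Tpi1 without any library except untreated library 2 (up to 0.131). As a whole the list did not pass (camera adjusted p = 0.418, median 0.07, mean -0.05). Nuclear-encoded subunits of oxidative phosphorylation were slightly higher: 16 of 74 rose and 0 fell (29 and 0 when adjusted over the list alone), with a list median of 0.13. The complex III subunits Uqcr10 and Uqcrq rose by 0.38 ± 0.07 and 0.34 ± 0.06, and Cox7a2 and Atp5h by 0.31 ± 0.07 and 0.28 ± 0.06. These small rises turned negative on log2(TPM + 1), at -0.06, -0.13, -0.08 and -0.12, where the median gene lay at -0.33. On TPM rescaled without short non-coding genes they were 0.32, 0.25, 0.30 and 0.26. Without untreated library 1 Cox7a2 and Atp5h missed the threshold (0.0561 and 0.0611). The 16 subunits risen became 4 without untreated library 1 and 7 without treated library 2. Camera gave adjusted p = 3.52e-10, 0.0604 on log2(TPM + 1), and with an estimated correlation adjusted p = 0.175. Of 13 mitochondrially encoded subunits 0 rose and 1 fell, also when adjusted over the list alone. This was mt-Nd6 (-1.29 ± 0.22, edgeR adjusted p = 0.0319), which lost its call without any library except untreated library 3 and treated library 1 (up to 0.101), and without untreated library 2 another member passed as higher. That list did not pass (camera adjusted p = 0.992), with a median of 0.03 and a mean of -0.03.

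Chaperone genes were lower in treated kidneys. Of 20 endoplasmic reticulum chaperones and associated genes 9 fell and 0 rose (15 and 0 when adjusted over the list alone). These 9 became 6 without untreated library 2 or 3 or treated library 1 or 2, and 11 without treated library 3. Herpud1, of the degradation pathway for misfolded proteins, fell from 322 ± 24.6 to 205 ± 23 CPM (log2 fold change -0.65 ± 0.08, edgeR adjusted p = 0.000233), and Creld2, Dnajb9 and Pdia4 by -0.91 ± 0.14, -0.65 ± 0.11 and -0.49 ± 0.07. The list's adjusted p was 8.92e-12 by camera, and adjusted p = 0.182 with an estimated correlation. Of 17 heat shock proteins 8 fell and 0 rose (14 and 1 when adjusted over the list alone). Hspa8, the constitutive cytosolic chaperone, fell from 2100 ± 157 to 1430 ± 211 CPM (-0.55 ± 0.10, adjusted p = 0.00327), and Stip1 and Hspb1 by -0.45 ± 0.09 and -0.98 ± 0.18. Hspb1 missed the threshold without untreated library 2 (adjusted p = 0.0503). The 8 fallen became 4 without untreated library 1, treated library 1 or treated library 4, and 3 without untreated library 2 or treated library 2, while 1 rose without treated library 3. This list had adjusted p = 7.43e-11 by camera, and adjusted p = 0.175 with an estimated correlation. In the integrated stress response 3 of 24 genes rose and 1 fell (4 and 3 when adjusted over the list alone; camera adjusted p = 0.298), and 2 rose and 2 fell without treated library 3. The serine synthesis gene Psat1 rose by 0.76 ± 0.09. Ddit4 (0.57) lost its call without untreated library 2 or 3 or treated library 1 or 4 (adjusted p up to 0.099), Aars (0.23, but -0.24 on log2(TPM + 1)) without any except treated library 2 (up to 0.0941), and Cebpg (-0.23) without any except treated library 3 (up to 0.102). Of 15 immediate early genes 0 passed by edgeR or over the list alone, with 3 at an unadjusted p under 0.05 and 1 called by DESeq2 (camera adjusted p = 0.181), and 1 rose without untreated library 1, treated library 3 or treated library 4.

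**Figure D2:**
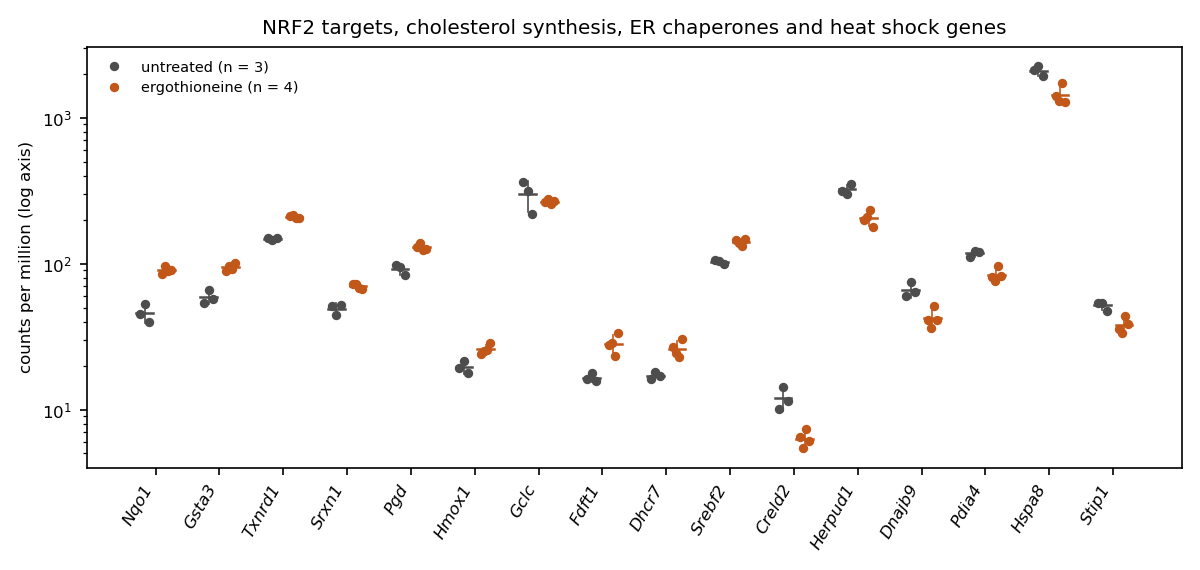
CPM (log axis) of 16 genes in the 3 untreated and 4 treated libraries; points are libraries, horizontal lines means and vertical lines SD. Nqo1, Gsta3, Txnrd1 and the cholesterol genes lay higher in every treated library, Creld2, Herpud1, Hspa8 and Stip1 lower, and Gclc overlapped.

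Tubular injury markers showed no common direction. Havcr1, which encodes KIM-1, was at 1.95 ± 1.06 CPM untreated and 1.57 ± 0.594 treated, and Lcn2, which encodes NGAL, at 2.72 ± 0.296 and 1.86 ± 0.537 (edgeR adjusted p = 0.724 and 0.21). Of 19 tested markers 3 rose and 0 fell (4 and 1 when adjusted over the list alone). The 3 were the cell cycle inhibitor gene Cdkn1a (log2 fold change 0.74 ± 0.15), Lgals3 (0.46 ± 0.10) and Spp1, which encodes osteopontin (0.27 ± 0.06, but -0.11 on log2(TPM + 1)). Lgals3 lost its call without untreated library 1 (adjusted p = 0.0684), and Spp1 without untreated library 3 or treated library 1 (0.0595 and 0.0599), and 5 markers rose without treated library 4, with 1 fallen without treated library 3. The list did not pass camera (adjusted p = 0.434), with a median of -0.10 and a mean of 0.00. Of 30 extracellular matrix and fibrosis genes 4 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.298). The elastin gene Eln rose by 0.73 ± 0.15, whereas the calls of Acta2 (0.44), Fbn1 (0.38), Col4a1 (0.21, but -0.20 on log2(TPM + 1)) and Thbs1 (-0.25) were each lost without untreated library 1 (0.0925, 0.175, 0.0695 and 0.0923). They were lost also without treated library 2 (Acta2), untreated library 3 or treated library 1, 2 or 4 (Fbn1), untreated library 3 or treated library 1 or 2 (Col4a1, up to 0.0708), and treated library 2 or 4 (Thbs1).

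Immune-related groups had few single genes past the test. Among inflammatory cytokines and NF-kB targets 1 of 18 rose and 2 fell (1 and 4 when adjusted over the list alone; camera adjusted p = 0.199). Tnfaip2 rose by 0.37 ± 0.07 (-0.21 on log2(TPM + 1)). The chemokine genes Cxcl10 (-1.06 ± 0.25) and Cx3cl1 (-0.22 ± 0.06) fell, but Cxcl10 missed the threshold without untreated library 1 or 3 (edgeR adjusted p = 0.0633 and 0.0686) and Cx3cl1 without any library except treated 3 and 4 (up to 0.134). Interferon-stimulated genes fell in 3 of 31 cases and rose in 0, also when adjusted over the list alone, while 30 of the 31 had a negative log2 fold change. Oas2 (-1.38 ± 0.33), Ifit1 (-0.91 ± 0.23) and B2m (-0.38 ± 0.09) were the 3. Oas2 lost its call without untreated library 3 or treated library 1 or 2 (up to 0.115), Ifit1 without any library except untreated 1 and treated 3 (up to 0.104), and B2m without any except treated 2 and 4 (up to 0.155). In all, 0 members fell without untreated library 3 or treated library 1, and 1 without untreated library 2 or treated library 2. This list had adjusted p = 6.39e-07 by camera, and adjusted p = 0.29 with an estimated correlation, and fry did not call it (0.0666). Of 15 macrophage and dendritic cell markers 2 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.0711). Ptprc, the pan-leukocyte gene for CD45, fell by -0.53 ± 0.11 and H2-Ab1 by -0.32 ± 0.09, the latter without a call when any library except treated library 4 was left out (up to 0.156). Without treated library 4, 4 of these markers fell.

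Among B and plasma cell markers 2 of 6 tested fell and 0 rose (4 and 0 when adjusted over the list alone). Ighg2b fell from 4.75 ± 1.08 to 0.703 ± 0.632 CPM and Jchain from 9.28 ± 3.23 to 3.23 ± 0.979 CPM (SD, n = 3 and 4; edgeR adjusted p = 0.00681 and 0.00626). Ighm stood at 38 ± 22.3 and 5.96 ± 2.47 CPM without passing (adjusted p = 0.0552), though DESeq2 called it (adjusted p = 3.58e-05), and so did edgeR without untreated library 3 (0.0275). Camera gave adjusted p = 2.07e-05 for the list, and with an estimated correlation adjusted p = 0.175. Of 4 tested T and NK cell markers 0 passed by edgeR, at an unadjusted p under 0.05, by DESeq2 or over the list alone (camera adjusted p = 0.576). Only 2 neutrophil markers reached the test and 0 passed by edgeR, DESeq2 or at an unadjusted p under 0.05, so that list had no test of its own.

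Cell cycle genes were higher from low levels. In this list 7 of 28 rose and 0 fell (15 and 0 when adjusted over the list alone). Mki67, the proliferation marker, rose from 3.62 ± 0.970 to 8.44 ± 2.13 CPM (log2 fold change 1.22 ± 0.24, edgeR adjusted p = 0.00822, but 0.0538 with the range of library index numbers as a block). The ribonucleotide reductase subunit Rrm2 (1.15 ± 0.18), the mitotic kinesin Kif11 (1.35 ± 0.27) and cyclin B1, Ccnb1 (2.06 ± 0.45), also rose. The 7 risen became 5 without untreated library 3 and 10 without treated library 1. Cdk1 lost its call without untreated library 2 or 3 (edgeR adjusted p up to 0.0531). A risen member not named here had no call in 5 such settings (up to 0.143, or too few counts to be tested). The list's adjusted p was 5.27e-11 by camera, and adjusted p = 0.175 with an estimated correlation.

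Calcium, phosphate and stone-related genes rose in 6 of 28 cases and fell in 1 (8 and 1 when adjusted over the list alone). Slc26a1, a sulfate and oxalate exchanger, rose by 0.31 ± 0.06 (edgeR adjusted p = 0.00577, but -0.12 on log2(TPM + 1)), and the citrate transporter Slc13a2 fell by -0.36 ± 0.07. The calcium channel Trpv5 rose by 0.42 ± 0.09, with a call lost without untreated library 1 (adjusted p = 0.0508). The 6 risen became 2 without untreated library 3 or treated library 1. Umod, the gene for the urinary glycoprotein uromodulin, stood at 2679.39 ± 109 and 2772.52 ± 181 CPM (0.05 ± 0.08, adjusted p = 0.783, and -0.32 on log2(TPM + 1)). The list had camera adjusted p = 0.00614, 0.0511 on log2(TPM + 1), and with an estimated correlation adjusted p = 0.33, and fry did not call it (0.0666). Of 23 genes of arginine, ornithine and polyamine metabolism 1 rose and 0 fell, also over the list alone, Gatm (0.24, but -0.13 on log2(TPM + 1)), with a call lost without any library except untreated library 1 (up to 0.116), and 1 gene fell without treated library 4. That list did not pass (camera adjusted p = 0.686, median -0.01, mean 0.00). Androgen-dependent kidney genes fell in 4 of 12 cases and rose in 0, also when adjusted over the list alone, and 1 rose without untreated library 1. Nudt19, a peroxisomal CoA diphosphatase, fell from 323 ± 11.3 to 147 ± 13.9 CPM (-1.13 ± 0.07, adjusted p = 3.84e-08), Cyp2j13 by -0.67 ± 0.08, Slc22a30 by -0.61 ± 0.07 and Slc22a28 by -0.42 ± 0.08. Of the 12 members 5 had a positive log2 fold change, and the list median was -0.11. Camera gave adjusted p = 1.16e-07, but 0.0760 on ranks and 0.175 with an estimated correlation.

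Some markers of the distal nephron rose. Of 10 intercalated cell markers 5 rose and 0 fell (6 and 0 when adjusted over the list alone), among them the anion exchanger gene Slc4a1 (40.1 ± 1.85 to 60.2 ± 7.94 CPM; log2 fold change 0.59 ± 0.09, edgeR adjusted p = 0.00154), Rhbg (0.46 ± 0.08) and the pendrin gene Slc26a4 (0.38 ± 0.08). For Atp6v1g3 (0.63) the call was lost without untreated library 1 or 3 or treated library 1 (up to 0.0995), and for Atp6v0d2 (0.38) without untreated library 3 or treated library 1 (up to 0.0864). Distal convoluted and connecting tubule markers rose in 3 of 8 cases and fell in 0 (5 and 0 when adjusted over the list alone), namely the kallikrein gene Klk1 (0.32 ± 0.06, but -0.07 on log2(TPM + 1)), Trpv5 and S100g (1.00 ± 0.19, lost without any library except untreated 1 and treated 4, up to 0.106, and with the index block, 0.0901). Thin limb markers rose in 3 of 7 cases and fell in 0 (4 and 0 when adjusted over the list alone). Among them, Fst (1.38) lost its call without untreated library 2 or 3 (up to 0.0728) and Slc14a2 (0.47) without untreated library 3 or treated library 2 or 4 (up to 0.0705). Thick ascending limb markers rose in 2 of 8 cases and fell in 0 (4 and 0 when adjusted over the list alone). These were the cotransporter gene Slc12a1 (0.34 ± 0.08) and Cldn10 (0.31 ± 0.09), which were -0.03 and -0.08 on log2(TPM + 1). Slc12a1 lost its call without untreated library 3 or treated library 1 or 2 (up to 0.0674), and Cldn10 without any library except untreated 2 and treated 4 (up to 0.147), while 4 members of this list rose without untreated library 2. The Trpv5 call was lost without untreated library 1 (0.0508). Camera adjusted p-values were 2.24e-06, 4.71e-06, 0.00147 and 0.00583 in this order. With an estimated correlation the adjusted p was 0.175 for the first 3 lists and 0.272 for the thick ascending limb. On ranks camera did not call the thin limb list (0.0566), nor on log2(TPM + 1) the thick ascending limb (0.0511).

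Other cell types of the kidney showed few changes. Of 10 podocyte markers 1 rose (0 without untreated library 2 or 3 or treated library 1, 2 or 3), and of 9 smooth muscle, pericyte and renin cell markers 1 rose, Acta2 (0 without untreated library 1 or treated library 2), with 0 fallen in both and the same counts over the list alone. Without untreated library 2, 1 podocyte marker fell. In the S1 and S2 proximal tubule list 1 of 11 rose, Gatm, and 1 fell, Slc13a3 (-0.31; 2 and 1 when adjusted over the list alone), and in the S3 list 1 of 8 fell, Slc7a13, also over the list alone. Slc13a3 missed the threshold without untreated library 1 or 3 or treated library 1 (edgeR adjusted p up to 0.0835), and Gatm without any library except untreated library 1 (up to 0.116). Without treated library 3 or 4, 2 S1 and S2 markers fell, and without untreated library 1, 1 S3 marker rose. Collecting duct principal cell, endothelial cell and urothelium markers had 0 of 9, 0 of 11 and 0 of 7 members past the test by edgeR, DESeq2, over the list alone or at an unadjusted p under 0.05. None of these 7 lists passed camera (adjusted p = 0.225, 0.164, 0.619, 0.434, 0.298, 0.99 and 0.304 in the order named), but fry called the collecting duct principal cell list as higher (adjusted p = 0.0367). The red blood cell list passed by camera (adjusted p = 0.00212, 0.0673 without treated library 4, and with an estimated correlation adjusted p = 0.175). In it 1 of 4 tested members rose (2 when adjusted over the list alone, and 2 without untreated library 1), and this was Slc4a1, shared with intercalated cells, while Alas2 stood at 0.01 ± 0.30. Of the adrenal cortex list 1 gene reached the test, Star, and did not pass, and of the skeletal muscle list 0 did.

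Adipocyte transcripts were lower in all 4 treated kidneys. Of 9 tested members of this list 7 fell and 0 rose, also when adjusted over the list alone. Ucp1 fell from 20.9 ± 6.22 to 0.835 ± 0.733 CPM (SD, n = 3 and 4; edgeR adjusted p = 0.0103, but 0.0748 with the replicate number as a block), with 306, 258 and 438 counts in the untreated libraries and 0, 12, 30 and 18 in the treated ones. Cidea, Plin1, Adipoq and Cidec had untreated means of 2.88, 3.92, 1.85 and 4.82 CPM and treated means of 0.104, 0.41, 0.25 and 1.01 CPM. Cfd (-1.35) and Adrb3 (-2.41) also fell, but Cfd missed the threshold without any library except untreated 3 and treated 2 (adjusted p up to 0.149) and Adrb3 without untreated library 3 (0.0709), while 1 member rose without untreated library 2. Lipe and Car3, at 27.7 and 57.1 CPM untreated, did not pass (-0.06 ± 0.12 and 0.31 ± 0.23). The list's adjusted p was 9.33e-17 by camera, and it kept its call with an estimated correlation (adjusted p = 0.0423). Against untreated library 3 alone the full difference was present in the median of the 7 fallen members (ratio 1.09, lowest 0.528). These members were called with that library among the untreated ones, which favours a ratio near 1, so the ratio decides nothing.

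**Figure D3:**
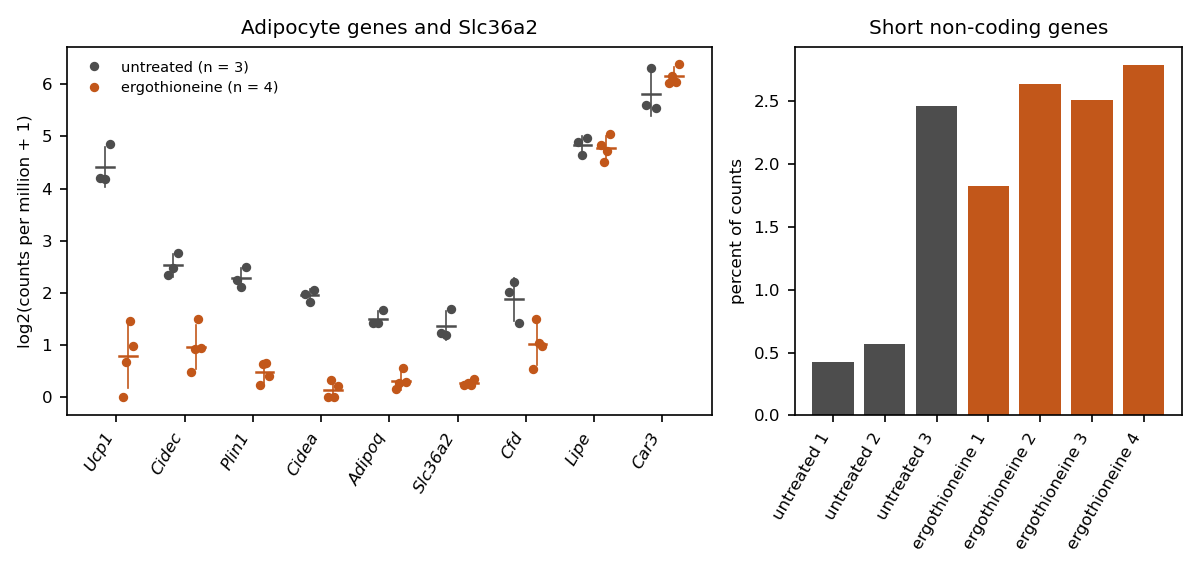
Left, log2(CPM + 1) of adipocyte list members and Slc36a2 in the 3 untreated and 4 treated libraries (points, libraries; lines, mean and SD); Ucp1, Plin1, Cidea and Adipoq lay lower in every treated library, Lipe and Car3 did not. Right, percent of counts from short non-coding genes per library, 0.428% and 0.571% in untreated libraries 1 and 2 and at least 1.83% in the others.

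In total 19 of 39 tested lists passed by camera with a preset inter-gene correlation, 11 upward and 8 downward, and 12 of them were pathway lists and 7 cell type lists. Only the clock and adipocyte lists also passed with a correlation estimated from these libraries, while fry, which asks whether a list's genes move one way without reference to other genes, called 17. Camera called up to 23 lists in other splits of the 7 libraries into 3 and 4, where edgeR called at most 161 genes, so the number of lists was within what regrouping gives and the number of genes was not.

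**Figure D4:**
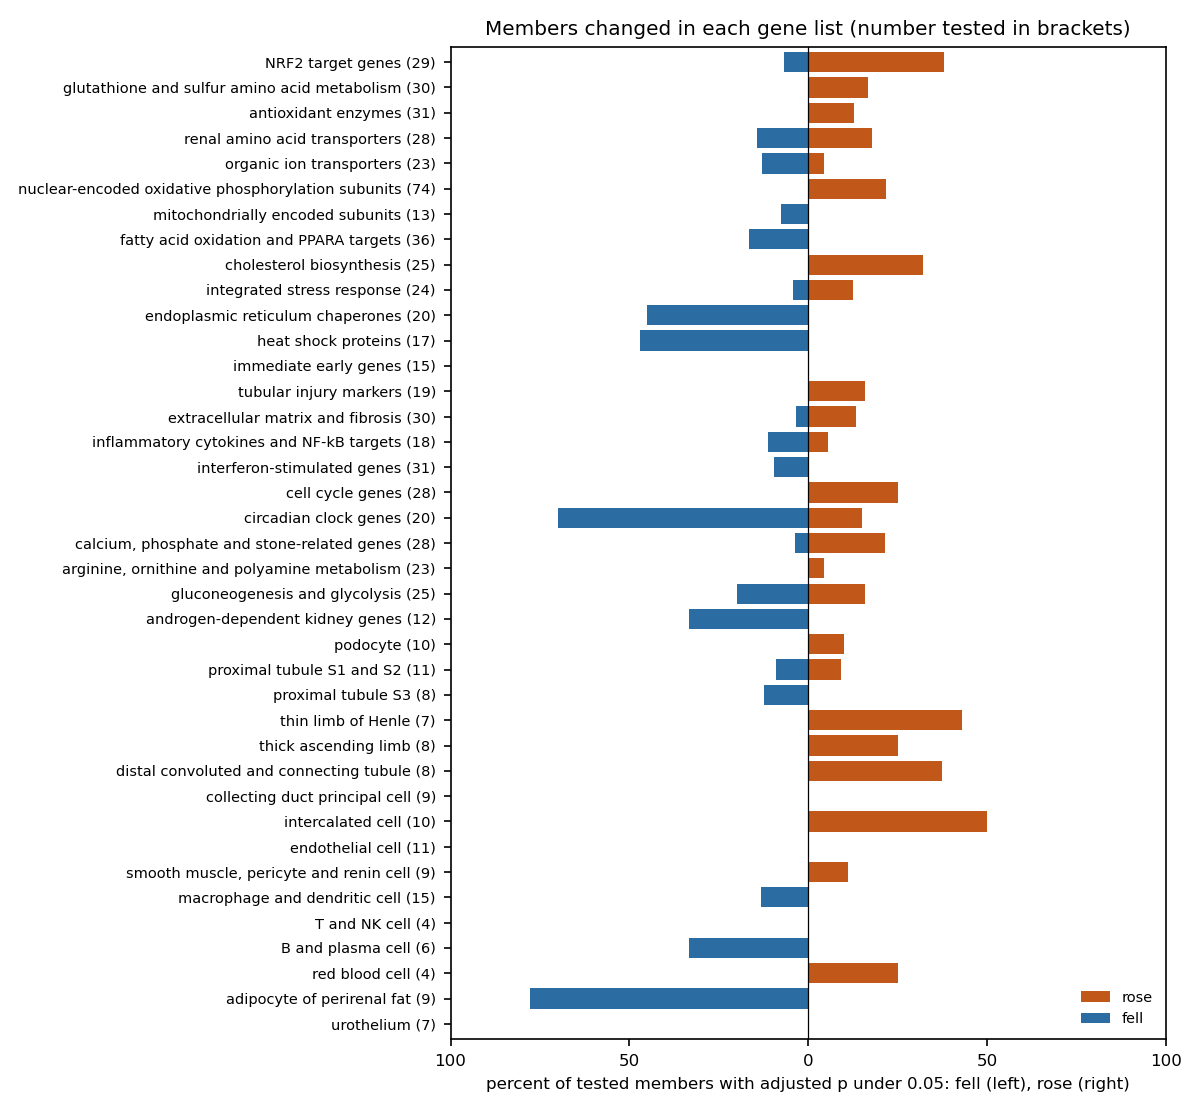
Percent of tested members of each of 39 gene lists with an edgeR adjusted p under 0.05 that rose (right) or fell (left) in 4 treated against 3 untreated kidneys; the number tested is in brackets. Clock (14 of 20) and adipocyte (7 of 9) genes had the highest shares fallen, and intercalated cell markers (5 of 10) the highest share risen.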

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

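Gaps within the 4 treated kidneys were compared with the range of their log2 CPM for 130 values, namely the tested named genes and 4 library measures, and 6 lay beyond Dixon's 95% critical value, where chance gives 6.5. Groups of 3 were not tested. Treated library 1 was lowest for the mitotic genes Cdk1 (0.681 CPM against 2.10 to 2.40 in the other 3; gap of 0.891 of the range) and Ccnb1 (1.42 against 1.93 to 2.02 CPM; 0.862). The same library was highest for the vitamin D receptor gene Vdr (403 against 349 to 353 CPM; 0.93) and the immunoglobulin gene Ighm (9.65 against 4.56 to 5.02 CPM; 0.873). Treated library 4 was highest for Nudt19 (168 against 139 to 141 CPM; 0.918), still far below the lowest untreated value of 310 CPM. It was lowest for the calcium-binding protein gene S100g (107 against 147 to 151 CPM; 0.93), above the highest untreated value of 80.3 CPM.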

How the results depend on the processing

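The settings without untreated libraries 1 and 2 and without short non-coding genes were chosen after the data were seen, the others before. Against the 1102 genes of edgeR, leaving out 1 library in turn gave 692 to 1103, with the lowest counts without treated library 1 and treated library 2 (710), the range of library index numbers as a block gave 921, and the replicate block gave 809, although the numbers did not pair the samples. Other counts were 1741 at an adjusted p under 0.1, 128 with a log2 fold change of at least 1, 64 on log2(TPM + 1) with no filter, 245 (122 higher, 123 lower) on TPM rescaled without short non-coding genes, and 556 without untreated libraries 1 and 2, where the lone untreated library is assumed to vary like the treated ones. Of 19 lists 2 passed with an estimated correlation, and 19 to 22 lists passed without single libraries. Apart from the estimated correlation, 10 of the 19 kept their call in every setting. Fry ended it for fatty acid oxidation, interferon and stone-related genes, camera on ranks for androgen-dependent genes and the thin limb, camera on log2(TPM + 1) for antioxidant enzymes, oxidative phosphorylation, stone-related genes and the thick ascending limb, and single libraries for fatty acid oxidation (untreated 1) and red blood cells (treated 4). For the difference of Slc7a9, 0.25 in log2 CPM, TPM gave -0.28. Of 110 called named genes 98 kept the call by every other count tool, scaling and filter and 73 without each library in turn. With the index block 95 kept it, and it ended for Pbk, Iqgap3, Got1, mt-Nd6, Aars, Cebpg, Hspb1, Acta2, Ifit1, B2m, Mki67, Gatm, Cldn10, S100g and H2-Ab1. With the replicate block 92 kept it, and it ended for Spp1, Cdk1, Mas1, Iqgap3, Ucp1, Got1, Mtr, Abcc2, mt-Nd6, Aars, Cebpg, Thbs1, Col4a1, Cx3cl1, Ifit1, Gatm, Slc13a3 and Atp6v1g3. On log2(TPM + 1) 98 had a value, of which 49 kept the call, 31 lost it and 18 turned. On that scale, where the median gene was shifted by -0.33, the sign turned for Slc7a9 (-0.28), Spp1 (-0.11), Umod (-0.32), Got1 (-0.14), Mtr (-0.084), Gpx4 (-0.035), Abcc2 (-0.33), Uqcrq (-0.13), Uqcr10 (-0.055), Cox7a2 (-0.076), Atp5h (-0.12), Aars (-0.24), Col4a1 (-0.20), Tnfaip2 (-0.21), Slc26a1 (-0.12), Gatm (-0.13), Slc12a1 (-0.034), Cldn10 (-0.083), Klk1 (-0.065), Vdr (-0.11), Cryab (-0.14), Kcnj1 (-0.19) and Alas2 (-0.25). Alas2 (0.01) also turned with voom sample weights (-0.052) and the replicate block (-0.011), and ranged from -0.21 to 0.46 without single libraries. On TPM rescaled without short non-coding genes, where the median shift was 0.0046, all 23 of these genes had the sign of the counts again. The cause was not tested for the other changes.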

Other observations

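Several of the smallest p-values belonged to genes outside the lists, chosen here after their values were seen. Ndrg1, a stress-responsive gene, rose from 1308.66 ± 187 to 2791.57 ± 135 CPM (SD, n = 3 and 4; log2 fold change 1.09 ± 0.09, edgeR adjusted p = 1.38e-06). Slc16a1, which encodes the monocarboxylate transporter MCT1, rose by 1.38 ± 0.09, the nuclear receptor gene Ppard by 1.33 ± 0.10, and the integrin genes Itgb6 and Itga6 by 0.84 ± 0.05 and 0.66 ± 0.06. Ddc, which encodes the enzyme that makes dopamine, rose by 0.77 ± 0.08. Mogat2, a monoacylglycerol acyltransferase gene, was lower by -1.54 ± 0.13, Coq10b by -0.94 ± 0.06, Esr1, which encodes an estrogen receptor, by -0.77 ± 0.09 and the prion protein gene Prnp by -0.65 ± 0.05. Nudt19 lies 81.1 kb from Slc7a9, and of 62 tested genes within 5 megabases of Slc7a9 6 were called (9.68%), against 7.15% elsewhere (Fisher's exact test, two-sided p = 0.452; within 1 megabase 4 of 18, p = 0.0356, the smaller of 2 windows tried).

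The tests below were chosen after the results were seen, except the second fat list and the splits of the samples, which were set before.

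The 7 libraries can be split into groups of 3 and 4 in 35 ways. Only the real split, 1 of 35, reached 1102 genes, and the highest other split reached 161, so no regrouping gave the real gene count. A share of 1 of 35 is the smallest that this test can reach. The other splits mix treated and untreated kidneys, which can lower their counts. The test also cannot tell ergothioneine from another difference between the groups. For the lists 5 of the 35 splits reached the real count of 19, with up to 23 lists in another split, so chance is not excluded for the number of lists called by camera at the preset correlation.

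Clock genes differed between the groups. The 17 called clock genes kept a median ratio of 1.08 of their difference against untreated library 3 alone (lowest 0.828), so their difference was also present there. They were called with that library among the untreated ones, which favours a ratio near 1. The ratio therefore does not decide on a library difference of untreated libraries 1 and 2. Of all 17, 14 followed the opposed arrangement of the clock's arms, with Arntl, Npas2 and Clock against Per2, Per3 and output genes, while 3 placed with Arntl, Cry1 and Rora among them, went against it; the arms were assigned after the directions were seen, so this count supports neither explanation, and a narrower set that left these 3 out tested nothing. Collection at different times of day and a clock shifted by ergothioneine both stay open and cannot be told apart because no collection time is given. As a hypothesis, chaperone, cholesterol and cell cycle genes may differ for the same reason, which these data do not test. No other difference between the groups, such as those of NRF2 targets, transporters or Pck1, is free of this limit.

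Adipocyte transcripts were lower in treated kidneys. A second list of 12 fat genes, written before its values were seen, had 9 tested members with a median log2 fold change of -1.29, of which 6 fell and 0 rose (among them Thrsp, -1.65, Plin4, -1.11, and Fabp4, -0.67, from 22.5 to 14.1 CPM). Against a fat source stand Cox7a1 (0.14) and Cpt1b (0.01) and, of the first list, Lipe (-0.06) and Car3 (0.31), none of which passed. The levels of Cpt1b, Lipe and Car3 (33.7, 27.7 and 57.1 CPM untreated) could hide a small share, but a high level does not account for Cox7a1 (2.99 CPM untreated, 3.28 treated). Against untreated library 3 alone the 7 called members of the first list kept a median ratio of 1.09 of their difference (lowest 0.528). They too were called with that library among the untreated ones, which favours a ratio near 1. A library difference of untreated libraries 1 and 2 is therefore not decided by this ratio. Perirenal fat carried with the untreated kidneys is a candidate explanation, and less fat around treated kidneys through ergothioneine itself stays open and untested.

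Short non-coding RNA was low in untreated libraries 1 and 2, at 0.428% and 0.571% of counts, with Rpph1 at 3982.98 and 4737.1 TPM against 30471 to 40067.1 in the other 5. The median log2 ratio between untreated libraries 1 and 2 and untreated library 3 was 0.00 (-0.0015) for 248 protein-coding genes under 500 nt. For 62 short non-coding genes it was -1.45. Length was the median of a gene's annotated transcripts, so the coding genes may be expressed from longer ones. Their length cutoff was also higher than that of the non-coding genes. A loss of short fragments is therefore not decided by this comparison. Untreated library 3, at 2.46%, lay within the treated range, but 1 library does not exclude ergothioneine as a source. The range of library index numbers stays open as well, since treated library 1 (index 44) had 0.692 of the mean share of the other treated libraries (1.83% against 2.64%), between both patterns. Single RNAs, chosen after their values were seen, went both ways. For Rn7s2 it had 16198.9 counts, near untreated libraries 1 and 2 (12365 and 12874), with at least 41987 in the others. For mt-Atp8 it also lay with them (2593 against 1983 and 2117, others at most 1535). For Rn7s1 it lay far from them (138326 against 19769.8 and 21648.8), as for Rn7sk and Rpph1. The RNA extraction of untreated libraries 1 and 2 may have differed, which was not tested.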
